A study of Mus musculus with 18 samples.

How the data were processed

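RNA of hippocampus, cerebellum and cortex from 3 Aldh5a1-/- and 3 wild-type mice was measured on 18 Affymetrix mouse expression arrays, 1 per animal and region. Replicates are separate animals per the labels, which give each an animal number in the sample title. The region was taken from the title and description, because the source label names hippocampus for every sample, and was checked against the data: 18 of 18 arrays lay closest to the other arrays of the named region. The values are probe set intensity on a linear scale, 1 column per array, already scaled by the authors to the same 2% trimmed mean before they were deposited (150.07 to 150.08 on the 18 arrays). The software that made them is not given in the sources used here. No other per-sample columns were in the table.

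Of 12488 probe sets, 66 controls were left out. Values under the 20th percentile of all values, a signal of 9.46, were raised to it, and log2 was taken. A probe set was kept when it lay above its array's 40th percentile on at least 3 of the 18 arrays, which left 8382. The annotation gave 1 gene symbol to 10855 probe sets, several to 396 and none to 1237, and 10839 of the first were found in the reference table (GRCm38 patch 6). The kept probe sets with 1 symbol numbered 7554 and named 6249 genes. Aldh5a1 was assigned 0 probe sets, so no test of it was run. Replicate arrays correlated on the log2 scale with Pearson r of 0.955 to 0.976 across probe sets, which are not independent replicates.

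KO and WT were compared in each region with limma 3.58.1 (R 4.3.3), fitting 6 group means to all 18 arrays (12 residual degrees of freedom), with an intensity trend in the empirical Bayes step. The mean of the regions was tested on 1 log2 mean per animal (4 residual degrees of freedom), and its signals are the geometric means over regions. The genotype by region interaction and the differences between WT regions were tested with limma's moderated F test, with the animal as a fixed block. Adjusted p are Benjamini-Hochberg values over all kept probe sets, with a threshold of 0.05, and all tests were two-sided. With 3 animals against 3, an exact permutation test of a single value cannot give a p under 0.1, and 2 groups of 3 lie wholly apart by chance in 10% of cases, so limma, which pools the spread over probe sets, was used. Signals are given as mean and SD of 3 arrays and log2 differences with limma's standard error. Arrays of 1 animal were checked for shared deviations: the residual correlation had a median of 0.135 within animals and -0.0159 between them, and fits with the animal as a replicate block are given beside the others.

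Named genes followed a fixed rule. For each comparison they were the genes past the threshold whose KO and WT values did not overlap, up to 12 per direction by size, filled to 8 by lowest p where fewer passed, and these fillers are said not to have passed. For each list they were up to 4 members past the threshold or otherwise the 2 of lowest p, for the interaction and the WT regions the 10 of lowest p, and for the chromosome 13 neighbours the 6 of lowest p. Genes given for a region where they were not named by the rule, such as Atf5 and Mobp in cerebellum or Nupr1 in cerebellum and cortex, were chosen after their values were seen. Gene lists, the design and most alternatives were fixed before the data were examined; the myelin and GABA lists were chosen knowing what is generally known of this mouse. Lists were tested with camera in limma at its preset correlation of 0.01, and again with an estimated correlation, with 1 probe set per gene, the brightest, and at least 5 kept genes, which 26 lists had. Neighbours of Aldh5a1 within 20 Mb on chromosome 13 were compared with other probe sets by Fisher's exact test.

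The fits were tested on simulated data with the spread of the real arrays and 50 changed probe sets per size. A log2 change of 1 was recovered for 68% in hippocampus, 74% in cerebellum, 70% in cortex, 92% in the mean of the regions and 30% in the interaction. All sizes, from 0.5 to 2, were planted together, which gave 148, 143 and 142 calls in hippocampus, cerebellum and cortex. Of these, 10, 8 and 5 were false. The real data gave only 10, 3 and 24 calls, so the adjusted threshold was stricter there and recovery can be lower. With no change, 1 call each was made in cortex and in the interaction and 0 in the other comparisons. The list test called 2 of 2 lists shifted by 0.5 and 0 others. Simulated probe sets and arrays varied independently, with no deviations shared within an animal or a list. The simulation therefore cannot test the preset correlation for lists whose members vary together, such as myelin (estimated correlation 0.475). Nor can it show how deviations shared by the arrays of 1 animal affect the calls.

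Alternatives tried were quantile normalization, median scaling, no floor, 16 added in place of the floor, no filter, a 60th percentile filter, no intensity trend, each animal left out in turn, the animal as a replicate block or no block, only the region's 6 arrays, the mean of all probe sets of a gene, an estimated correlation within lists and a window of 5 Mb. Leaving out the cerebellum array of WT animal 3405 was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.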

Results

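Gene expression was measured in the brains of mice lacking Aldh5a1 (Aldh5a1-/-, here KO) and of wild-type mice (WT). Aldh5a1 encodes succinate semialdehyde dehydrogenase, the mitochondrial enzyme that carries out the last step of GABA breakdown. Hippocampus, cerebellum and cortex of each of 6 mice, 3 KO and 3 WT, were each hybridised to 1 Affymetrix mouse array, which gave 18 arrays in 6 groups of 3. The KO mice carry the numbers 3363, 3389 and 3403 in the labels, and the WT mice 3405, 3406 and 3396. Each array gave a scaled intensity, called signal here, for 12488 probe sets, and 8382 of them were kept for testing. Median signal per array lay between 53.5 and 64.8. The question asked throughout is which transcripts differ between KO and WT tissue, in each region and over all 3. Aldh5a1 itself could not be read: 0 probe sets of the array were assigned to it, so the genotype was taken from the labels alone.

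Regional identity was plain in WT tissue. Gabra6, the GABA-A receptor subunit of cerebellar granule cells, had a signal of 2774 ± 96.9 (SD, n = 3) in cerebellum on 1 probe set, while its means in hippocampus and cortex, 3.05 and 5.76, lay under the floor of 9.46. Another Gabra6 probe set read 2292 ± 184 in cerebellum, 14.7 ± 3.87 in hippocampus and 24.3 ± 9.04 in cortex. Cbln1, a synaptic organiser secreted by granule cells, reached 2734 ± 268 in cerebellum against 101 ± 14.7 in hippocampus and 124 ± 21.5 in cortex. Tbr1, a transcription factor of glutamatergic neurons, was highest in cortex at 1219 ± 235, with 467 ± 77.1 in hippocampus and 4.95 ± 2.30 in cerebellum. Nrgn, a postsynaptic calmodulin-binding protein, read 1236 ± 176 in cortex, 1075 ± 158 in hippocampus and 6.33 ± 4.14 in cerebellum. Ptk2b, a calcium-sensitive kinase, and the sialyltransferase gene St6galnac5 were highest in hippocampus, 2.27-fold and 2.26-fold above cortex. The neuropeptide gene Cck and the chemokine gene Cx3cl1 were 9.45-fold and 9.98-fold higher in their highest region than in cerebellum. Ppp1r17, a Purkinje cell phosphatase inhibitor, read 821 ± 64.3 in cerebellum, and D430019H16Rik was 1.64-fold higher in hippocampus than in cortex.

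By limma's moderated F test with the animal as a block, 3299 probe sets (39.4% of 8382) differed between the WT regions at an adjusted p under 0.05, and 3320 without the block. Without WT animal 3406 the count was 1596. Of the marker genes fixed for each region, 12 of 13 cerebellar, 6 of 8 hippocampal and 5 of 5 cortical ones passed and were highest in their own region. The exceptions were Zic2, which did not pass (adjusted p = 0.873), and Tdo2 and Neurod2, hippocampal markers that were highest in cerebellum. All 18 arrays were closest to the other arrays of the region that their title names, although another label calls every sample hippocampus.

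In KO hippocampus, Atf5, Nupr1 and Slc3a2 were higher, and Gsn, Mobp and Mag were lower. Atf5, a transcription factor of the stress response, rose 5.30-fold, from 54.9 ± 7.09 in WT to 302 ± 113 in KO (SD, n = 3). Nupr1, a stress-induced nuclear protein, rose from 30.7 ± 20.6 to 244 ± 39.3, with 1 WT array, that of 3405, under the floor. Its log2 difference on floored values was 3.23, which is 9.39-fold and more than the ratio of these means. Without animal 3405 it was 2.51. Slc3a2, the heavy chain of large neutral amino acid transporters, rose 1.62-fold, from 878 ± 47.6 to 1428 ± 189. Gsn, an actin-severing protein abundant in oligodendrocytes, was 3.51-fold lower, at 181 ± 32.9 against 642 ± 161.

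**Figure D1:**
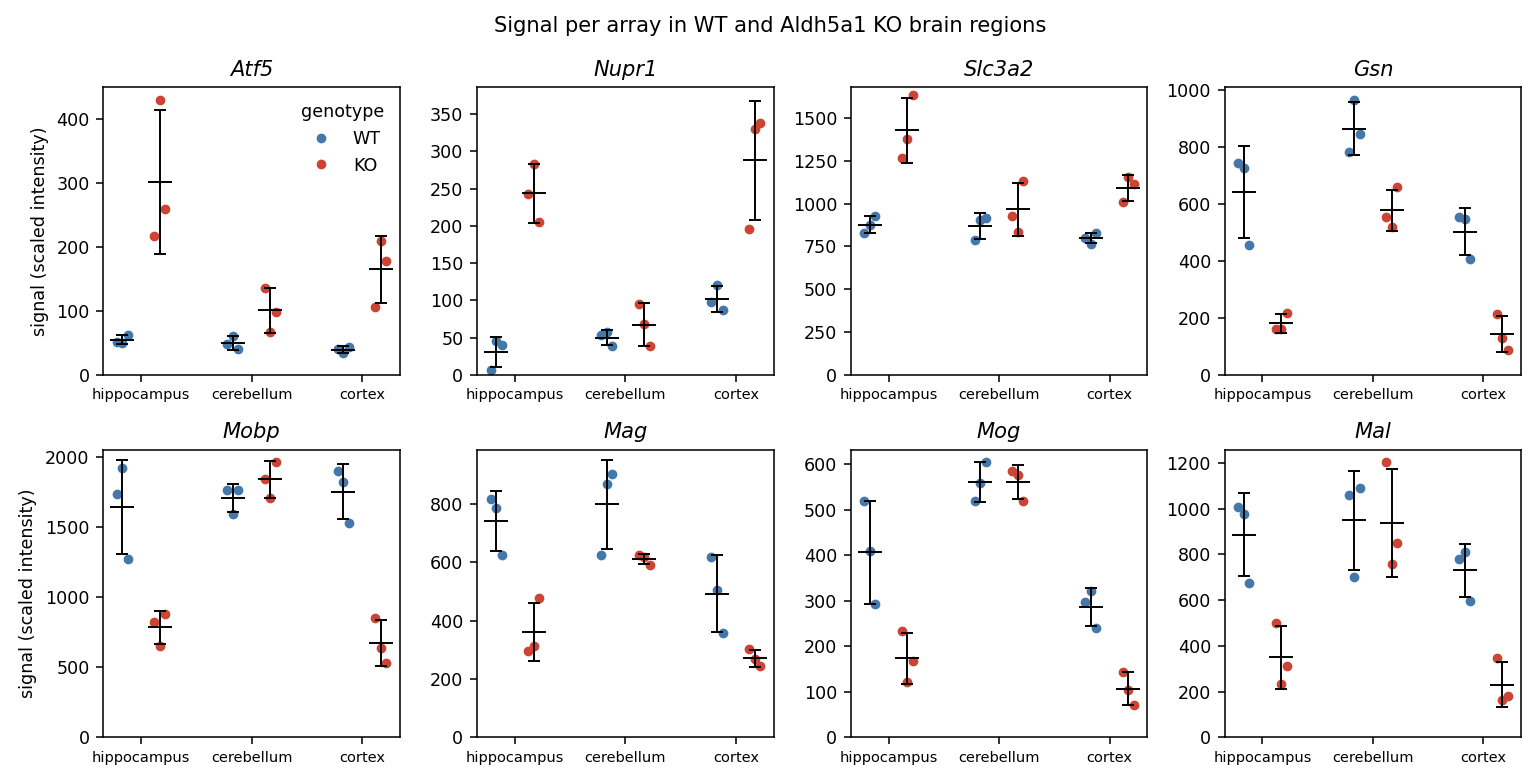
Signal (scaled intensity, linear axis from 0) of 8 genes on each of the 18 arrays, WT in blue and KO in red, by region; the horizontal line is the group mean and the bars are the SD (n = 3). In hippocampus Atf5 lay between 217 and 430 in KO and between 49.7 and 63.0 in WT, and in cerebellum Mog lay between 519 and 586 in KO and between 519 and 605 in WT.

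The myelin and mature oligodendrocyte list fell in KO hippocampus by camera with its preset correlation: all 14 measured members were below 0, with a median log2 difference of -0.74 and an adjusted p of 1.18e-19. The call was lost at adjusted p = 0.0714 with an estimated correlation. Of these, 3 fell, 0 rose and 11 did not pass over all probe sets, and 10 fell when adjusted over the list alone. The 3 were Gsn, and Mag and Mobp, which encode proteins of the myelin sheath. Mobp read 786 ± 117 in KO and 1643 ± 335 in WT, 2.08-fold lower. Mag read 362 ± 100 against 743 ± 103, but another Mag probe set had a log2 difference of 0.59. Mog and Mal, also myelin proteins, did not pass, with log2 differences of -1.24 ± 0.24 (SE) and -1.39 ± 0.29 and adjusted p of 0.0569 and 0.0846. With the animal as a block Mog passed (0.0496) and Mal did not (0.0536).

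Genes outside the myelin list were lower in hippocampus as well. Cacna1g, a low-voltage-activated calcium channel, fell 3.34-fold to 12.8 ± 2.66, and Septin4, a filament-forming GTPase, fell on 1 probe set to 14.2 ± 7.33, at least 3.19-fold lower, with 1 of the 3 KO arrays under the floor. Kcne1l, a potassium channel accessory subunit, was at least 4.44-fold lower, since all 3 KO arrays were under the floor. The cholesterol synthesis list fell (14 of 16 members below 0, median -0.40, adjusted p = 3.46e-07, and adjusted p = 0.216 with an estimated correlation). None of its members passed over all probe sets in limma, and 3 did when adjusted over the list alone, among them Hmgcs1 (-0.73 ± 0.17), which feeds the pathway, and Idi1 (-0.79 ± 0.22). Without KO animal 3363 the list's median was -0.26.

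Glial activation lists moved the other way in KO hippocampus. All 10 reactive gliosis genes were above 0 (median 0.36, adjusted p = 0.000128, and 0.252 with an estimated correlation), and 4 rose when adjusted over the list alone. Among them Osmr, the oncostatin M receptor, had a log2 difference of 1.04 ± 0.23 and Gfap, the astrocyte filament protein, 0.99 ± 0.29; neither passed over all probe sets (adjusted p = 0.112 and 0.293). All 12 microglia genes were above 0 (median 0.19, adjusted p = 0.00144, and 0.288 with an estimated correlation). The lysosomal protein gene Cd68 (0.62 ± 0.15) and the adaptor gene Tyrobp (0.93 ± 0.27) rose when adjusted over the list alone. Without KO animal 3403 the microglia list had a median of 0.07 and an adjusted p of 0.124, and without 3363 a median of 0.31. The mitochondrial oxidative phosphorylation list was lower by a small amount (32 of 36 members below 0, median -0.09, adjusted p = 0.000802, and 0.252 with an estimated correlation), and its adjusted p was 0.127 after quantile normalization. The vascular endothelium list was also lower (9 of 11 below 0, median -0.22, adjusted p = 0.0121, and 0.252 with an estimated correlation), with adjusted p up to 0.0825 when KO animal 3363 or 3389 was left out, and medians of -0.10 without 3363 and -0.40 without 3403.

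Of the genes with the lowest p among those that did not pass in hippocampus, the translation repressor gene Eif4ebp1 had a log2 difference of 1.92 ± 0.40 (adjusted p = 0.0914). The serine synthesis gene Psph had 0.52 ± 0.12 (0.141), the leukocyte surface gene Cd52 had 1.11 ± 0.25 (0.124) and the anchoring protein gene Akap8 had 1.57 ± 0.36 (0.124), though its other 2 probe sets had 0.42 and -0.36.

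By limma, 3 probe sets were higher and 7 lower in KO hippocampus at an adjusted p under 0.05, with the animal as a block 3 and 8, and 705 had an unadjusted p under 0.05 where 419.1 would by chance. Adjusted p was 0.000953 for Atf5, 0.00165 for Nupr1, Gsn and Cacna1g, 0.00349 for Kcne1l, 0.00646 for Mobp, 0.0101 for Slc3a2, 0.0113 for Septin4 and 0.0320 for Mag. The count higher was 7 without animal 3363. The count lower was 11 without 3403, 1 without 3405, 4 without 3406 and 18 without 3396, and the region's own 6 arrays gave 0 higher and 1 lower. Atf5, Nupr1 and Cacna1g passed without any 1 animal, but not on the region's own 6 arrays (adjusted p = 0.137, 0.263 and 0.235). Of the genes named as called in hippocampus, only Kcne1l passed on those arrays. Gsn and Kcne1l did not pass without 3405, and Slc3a2 did not without 3405 or 3406. Mobp, Mag and Septin4 did not without 3 or 4 of the animals, 3405 among them. With no intensity trend Slc3a2 and Mag did not pass (adjusted p = 0.0580 and 0.117), and with no filter Septin4 and Mobp (both 0.0543) and Mag did not.

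KO cortex also had higher Atf5 and lower myelin genes. Atf5 rose 4.03-fold, from 39.6 ± 5.24 to 165 ± 52.6 (SD, n = 3). Mobp was 2.64-fold lower, at 674 ± 165 against 1752 ± 197, and Gsn was 3.71-fold lower, at 143 ± 63.8 against 502 ± 83.4. Mal, a proteolipid of myelin, fell from 730 ± 117 to 231 ± 99.8. Mog, the outermost myelin glycoprotein, fell from 286 ± 41.3 to 107 ± 36.7.

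The myelin and mature oligodendrocyte list fell in cortex, with all 14 members below 0 and a median log2 of -0.83. Of these, 7 fell, 0 rose and 7 did not pass, and 10 fell when adjusted over the list alone. Its camera adjusted p was 2.01e-22, and 0.0446 with an estimated correlation. In this region the Gapdh 3'/5' ratio, given below, also differed between the genotypes. The other members that fell were Nkx6-2, an oligodendrocyte transcription factor (67.7 ± 4.92 to 20.8 ± 8.77), Mbp, the main cytoplasmic myelin protein (3359 ± 455 to 1893 ± 110), and Cldn11, the tight junction protein of myelin (762 ± 79.2 to 469.5 ± 58.3). Other probe sets of Mbp and Cldn11 had log2 differences of 0.09 and 0.04. Outside the list, Lpar1, a lysophosphatidic acid receptor, fell 2.12-fold and Scd1, which makes monounsaturated fatty acids, fell 2.16-fold, although 1 of the other Scd1 probe sets differed by 0.46 on the log2 scale. Anln, an actin-binding protein of cell division, fell 2.33-fold, Slc25a53, a mitochondrial carrier family member, fell 1.88-fold, and Lsm2, a component of the splicing machinery, fell 4.24-fold.

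Beside Atf5, 3 named genes rose in cortex. They were Stat6, a cytokine-activated transcription factor (3.10-fold, to 48.3 ± 14.8), Tbc1d22a (1.68-fold) and Hap1, a huntingtin-binding trafficking protein (1.68-fold). Another Tbc1d22a probe set differed by 0.16 on the log2 scale. Nupr1 did not pass in cortex, at 288 ± 79.7 in KO and 102 ± 16.9 in WT, and Slc3a2 read 1093 ± 76.5 and 798 ± 30.4. Foxn2, Nt5dc2, Nfyc and Atraid, next by p, did not pass (adjusted p = 0.0552, 0.0554, 0.0554 and 0.0711). A further 4 probe sets that the annotation used here does not assign to 1 gene passed, 1 of them higher, with a log2 difference of 1.54 ± 0.25, and 3 lower, with -1.75 ± 0.33, -1.50 ± 0.21 and -1.42 ± 0.21.

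Other lists that passed in cortex had medians nearer to 0. Heat shock genes were lower (9 of 11 below 0, median -0.31, adjusted p = 0.00086, and 0.326 with an estimated correlation). Members passing over the list alone numbered 5, among them the chaperonin Hspd1 (-0.35 ± 0.10) and Hsp90aa1 (-0.43 ± 0.13). Cholesterol synthesis genes were lower (13 of 16 below 0, median -0.31, adjusted p = 0.00117, and 0.524 with an estimated correlation), and 4 passed over the list alone, including Idi1 (-0.71 ± 0.22) and Ebp (-0.46 ± 0.15). Without KO animal 3363 the list's median was -0.17 (adjusted p = 0.0301). Microglia genes were higher (11 of 12 above 0, median 0.25, adjusted p = 0.00624, and 0.567 with an estimated correlation), led by Cd68 (0.56 ± 0.15), though not without KO animal 3389 or 3403 (adjusted p up to 0.185), and its median was 0.41 without 3363 and 0.13 without 3403. Glucocorticoid-responsive genes (median -0.12, adjusted p = 0.0341, and 0.588 with an estimated correlation) included Sgk1 (-0.63 ± 0.16), a kinase induced by corticosteroids. Interneuron genes (median -0.17, adjusted p = 0.0402, and 0.326 with an estimated correlation) included the tachykinin gene Tac1 (-1.09 ± 0.28), and oxidative phosphorylation genes had a median of -0.07 (adjusted p = 0.0256, and 0.579 with an estimated correlation). The last 3 lists had adjusted p of 0.0566, 0.0653 and 0.128 after quantile normalization, and of up to 0.286, 0.235 and 0.186 with 1 animal left out (3363, 3403 or 3396 for glucocorticoid-responsive genes, any but 3406 or 3396 for interneuron genes, any but 3403 or 3396 for oxidative phosphorylation). The glucocorticoid median was -0.26 without 3363, -0.22 without 3389 and -0.20 without 3396, and that of oxidative phosphorylation -0.04 without 3363 and -0.13 without 3403. Reactive gliosis genes did not pass in cortex (median 0.15, adjusted p = 0.344).

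**Figure D2:**
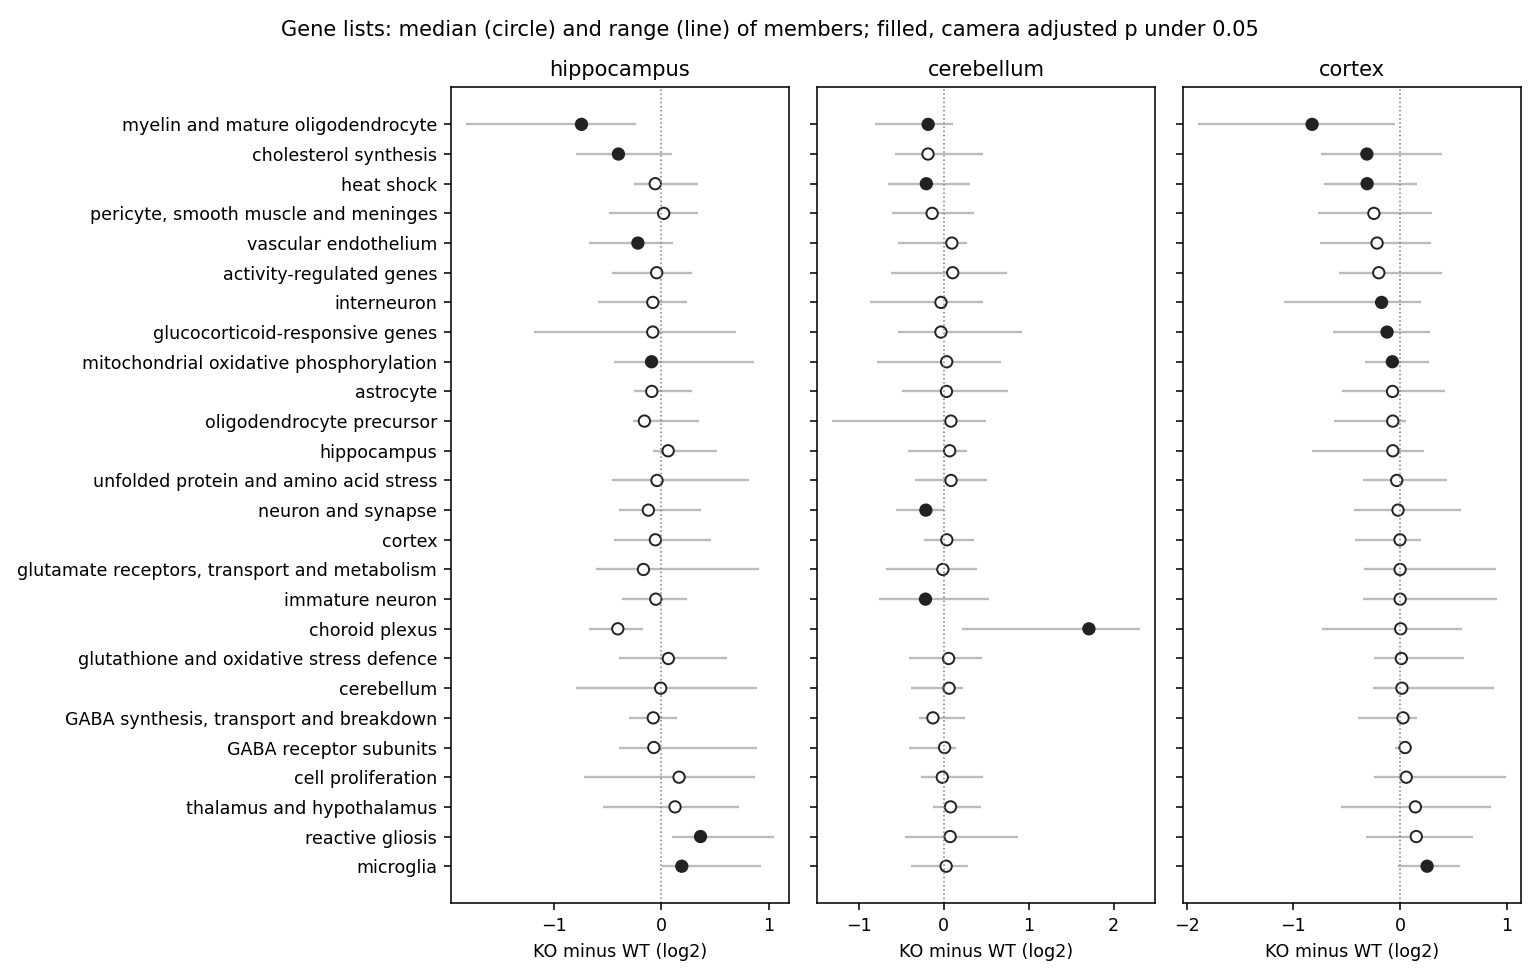
KO minus WT log2 difference of each tested gene list in the 3 regions (x axis, log2; its range differs between panels): the circle is the median of the members and the line their range, filled where the camera adjusted p was under 0.05 with the preset correlation. The myelin list lay at -0.74 in hippocampus, -0.83 in cortex and -0.18 in cerebellum.

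By limma, 5 probe sets were higher and 19 lower in KO cortex, with the block 5 and 20, and 859 had an unadjusted p under 0.05. Adjusted p was 0.000758 for Mobp, 0.00178 for Gsn, 0.00236 for Atf5, 0.00251 for Lsm2, 0.00578 for Lpar1, 0.00782 for Mal and Mog, and 0.0083 for Anln and Scd1. It was 0.0114 for Nkx6-2, 0.0214 for Mbp, 0.0253 for Hap1 and Slc25a53, 0.0267 for Tbc1d22a, 0.0305 for Cldn11 and 0.0440 for Stat6. The count higher was 2 without animal 3389, 3403 or 3405 and 8 without 3406. The count lower was 8 without 3403, 4 without 3405 and 10 without 3406, and the region's own 6 arrays gave 1 higher and 2 lower. Atf5, Gsn and Mobp passed without any 1 animal, but not on the region's own 6 arrays (adjusted p = 0.0915, 0.121 and 0.0899). Of the genes named as called in cortex, only Scd1 passed on those arrays. Lsm2 and Scd1 did not pass without 3405, Lpar1 not without 3403 or 3405, and Mal, Mog and Nkx6-2 not without 3403, 3405 or 3406. Anln, Mbp, Cldn11, Slc25a53, Hap1, Tbc1d22a and Stat6 did not pass without 4 or more of the 6 animals in turn, 3405 among them. With no intensity trend Hap1, Mbp and Cldn11 did not pass (adjusted p = 0.0708, 0.0833 and 0.0906), and with no filter these, Mal, Mog, Nkx6-2, Scd1 and Stat6 did not (0.0501 to 0.0730). The ratio of 3' to 5' Gapdh signal, a measure of RNA integrity, was 0.804 ± 0.00773 on the KO cortex arrays and 0.903 ± 0.0202 on the WT ones, while the same ratio for actin was 1.77 ± 0.124 and 1.77 ± 0.140.

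Hippocampus and cortex shared 4 probe sets that passed in the same direction, where independent regions would give 0.00179 for higher and 0.0159 for lower ones. The regions are not independent, since both come from the same 6 animals, so part of the excess may be shared deviations of the animals. Over all 8382 probe sets the log2 differences of both regions correlated at r = 0.112, inside the 0.0357 to 0.221 of the 9 other splits of the animals into 3 and 3. The shared probe sets were 1 each for Atf5 and Gsn and 2 for Mobp. Neither region shared a probe set with cerebellum.

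In KO cerebellum, 3 genes passed and all were lower. Syt5, a calcium sensor of vesicle release, fell 3.39-fold, from 94.6 ± 18.9 to 30.4 ± 16.1 (SD, n = 3). Lst1, a leukocyte transcript, fell 2.99-fold, from 49.6 ± 9.65 to 16.4 ± 1.28, and Rbm42, an RNA-binding protein, fell 1.63-fold, from 545 ± 44.5 to 334 ± 30.4. Myelin genes named above did not pass in cerebellum: Mobp read 1840 ± 129 in KO and 1708 ± 101 in WT, Mog 561 ± 36.7 and 561 ± 43.1, and Gsn 577 ± 72.1 and 864 ± 93.3. Atf5 read 101 ± 34.7 and 50.01 ± 10.5, and did not pass either.

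Neuron and synapse genes fell together in cerebellum by a small amount (17 of 18 below 0 and 0 above, median -0.21, adjusted p = 1.42e-05, and 0.295 with an estimated correlation). The remaining member had a log2 difference of exactly 0, as values all raised to the floor would give. Of the 18 members, 0 passed over all probe sets in limma and 7 when adjusted over the list alone. Vamp2 (-0.34 ± 0.10) and Syp (-0.56 ± 0.17), both synaptic vesicle proteins, were lowest by p. Choroid plexus genes were higher (7 of 7 above 0, median 1.71, adjusted p = 0.00177, and 0.874 with an estimated correlation), among them the transporter gene Slc4a5 (1.72 ± 0.54) and the folate receptor gene Folr1 (1.71 ± 0.59). Without WT animal 3405 that list had a median of 1.13 and an adjusted p of 0.128, and without 3406 a median of 0.97. Ttr, the most abundant transcript of choroid plexus, ranged from 266 to 1237 on the KO cerebellum arrays and from 27.0 to 1112 on the WT ones, so its spread within each genotype was wide. Myelin genes (median -0.18, 11 of 14 below 0, adjusted p = 0.0270, and 0.887 with an estimated correlation), immature neuron genes (median -0.21, adjusted p = 0.0482, and 0.874 with an estimated correlation) and heat shock genes (median -0.20, adjusted p = 0.0486, and 0.874 with an estimated correlation) were lower. These 3 lists had adjusted p of 0.0701, 0.0716 and 0.0716 after quantile normalization, and of up to 0.179, 0.794 and 0.505 with 1 animal left out (3389 or 3396 for myelin, 3363, 3405 or 3396 for immature neuron, 3363, 3389 or 3405 for heat shock). The myelin median was -0.28 without 3363 and -0.11 without 3389 or 3396, and that of heat shock -0.11 without 3363.

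**Figure D3:**
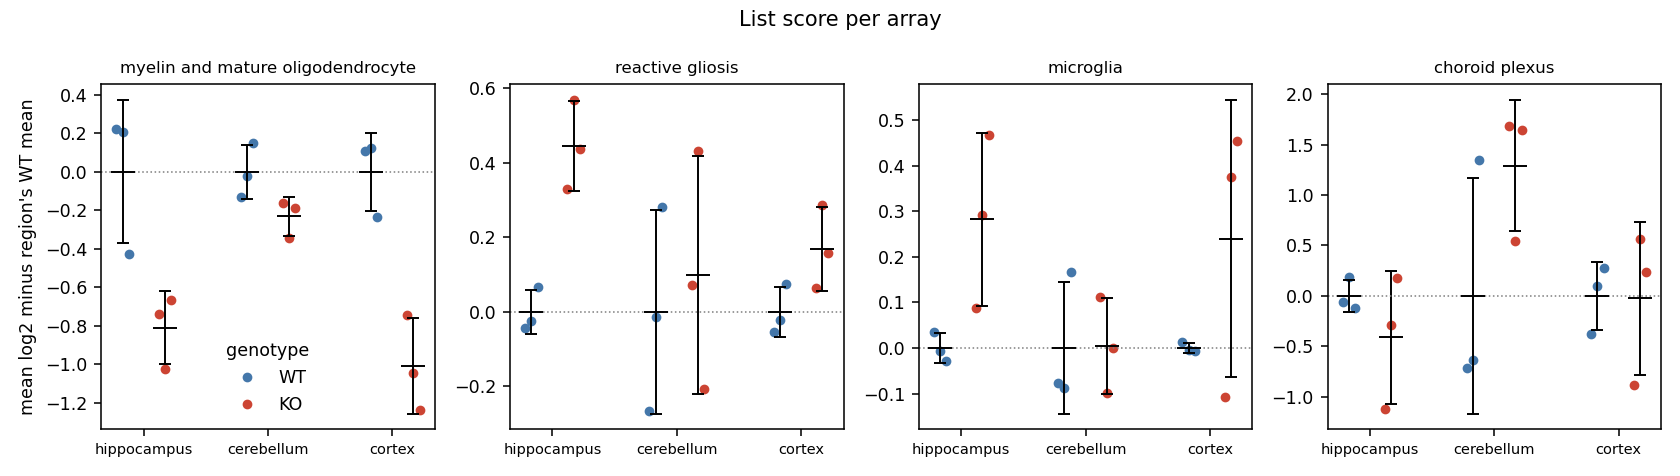
Mean log2 value of the members of 4 gene lists on each array, minus the region's WT mean (y axis, log2), WT in blue and KO in red; lines are group means and bars the SD (n = 3). The myelin score of the KO arrays lay between -1.03 and -0.67 in hippocampus and between -0.35 and -0.16 in cerebellum, and the choroid plexus score of the WT cerebellum arrays ranged from -0.71 to 1.35.

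Genes next by p in cerebellum did not pass. Higher in KO were the somatostatin receptor gene Sstr2 (1.68 ± 0.33, adjusted p = 0.0668), the mRNA decay factor Zfp36l1 (1.11 ± 0.22, 0.0668), the ribosomal protein gene Rps19 (0.88 ± 0.18, 0.0720), Midn (0.51 ± 0.11, 0.0720) and the RNA helicase gene Ddx6 (1.81 ± 0.39, 0.0725). Dnajb6, Cep350 and Acot13 each had an adjusted p of 0.111. Lower were Wdr6 (-0.84 ± 0.15), the phosphatase gene Ppp5c (-0.80 ± 0.15) and Ndrg1 (-0.73 ± 0.14), each with an adjusted p of 0.0619, and Rab8b (-1.53 ± 0.31) and Nsf (-0.79 ± 0.16), both of membrane traffic, at 0.0720. The other 2 Sstr2 probe sets had log2 differences of -0.29 and 0.13.

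By limma, 0 probe sets were higher and 3 lower in KO cerebellum, the same counts with the block, and 1013 had an unadjusted p under 0.05. Adjusted p was 0.00688 for Lst1, 0.00881 for Syt5 and 0.0220 for Rbm42. These counts depended on 1 animal: without WT animal 3405 they were 54 higher and 67 lower, and with only its cerebellum array left out, chosen after seeing the data, 62 and 102. The count higher was 1 without 3363 and 6 without 3396; the count lower was 0 without 3389 or 3406 and 6 without 3396, and 0 on the region's own 6 arrays. Syt5 and Lst1 did not pass without 3389 or 3406, nor Rbm42 without 3363, 3389, 3403 or 3406. With no intensity trend Syt5 and Rbm42 did not pass (adjusted p = 0.0579 and 0.0946), nor did Syt5 with no filter (0.0672).

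Averaged over the 3 regions of each animal, Atf5 and Nupr1 were higher and Gsn, Mog, Mobp and Mag were lower. Atf5 rose 3.48-fold, from 47.3 ± 1.01 in WT to 165 ± 17.8 in KO (geometric mean over regions; SD, n = 3 animals), and Nupr1 rose 3.21-fold, from 52.0 ± 15.5 to 163 ± 23.6, though in cerebellum it did not pass, at 67.2 ± 28.6 in KO and 50.1 ± 9.55 in WT (log2 difference 0.35 ± 0.44). Rps19 rose 1.38-fold, from 413 ± 14.7 to 568 ± 35.3. Gsn fell 2.69-fold, from 650 ± 98.1 to 240.3 ± 24.2.

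Mog fell 1.87-fold, Mobp 1.72-fold and Mag 1.69-fold, although another Mag probe set had a log2 difference of 0.31. With Gsn they were the 4 of 14 myelin list members that fell, while 10 did not pass and 12 fell when adjusted over the list alone. Gamt, the last enzyme of creatine synthesis, fell 1.65-fold, from 209.8 ± 4.76 to 127 ± 14.98, and Smyd2, a lysine methyltransferase, fell 2.28-fold, though another probe set of each differed by -0.06 and -0.03 on the log2 scale. Ndrg1, a stress- and differentiation-related gene, fell 1.42-fold and Ptgds, the brain prostaglandin D synthase, fell 1.37-fold. Mthfd2, of mitochondrial folate metabolism, Zfp36l1, Slc3a2, Eif4ebp1 and Astn1, a neuron-glia adhesion gene, did not pass, with log2 differences of 0.75 ± 0.13, 0.66 ± 0.12, 0.43 ± 0.08, 1.21 ± 0.25 and 1.13 ± 0.24 (adjusted p = 0.0602, 0.0780, 0.0830, 0.153 and 0.155).

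By limma on 1 mean per animal, 3 probe sets were higher and 12 lower, and with all 18 arrays and the animal as a block 10 were higher and 28 lower; 850 had an unadjusted p under 0.05. With no intensity trend 1 was higher and 0 lower, and with no filter 2 and 3; of the genes named here only Atf5 passed in either (adjusted p = 0.00273 and 0.0327), while Gsn had 0.0586 and 0.203, Mag 0.160 and 0.244, Mobp 0.160 and 0.309, and Mog 0.255 and 0.421. Adjusted p was 0.000128 for Atf5, 0.000804 for Gsn, 0.00767 for Mag, 0.00893 for Mobp, 0.00973 for Nupr1, 0.0266 for Gamt, 0.0348 for Smyd2, 0.0411 for Ptgds, 0.0423 for Ndrg1 and 0.0437 for Mog and Rps19. With the block, Mthfd2, Zfp36l1, Slc3a2 and Eif4ebp1 passed (adjusted p = 0.00479, 0.0322, 0.00522 and 0.0312), while Ptgds and Rps19 did not (0.246 and 0.101). The count higher was 1 without animal 3389 or 3403 and 7 without 3396. The count lower was 5 without 3389, 2 without 3403, 1 without 3405 or 3406 and 20 without 3396. Atf5 and Gsn passed without any 1 animal, Nupr1 not without 3389 or 3403, Mag not without 3405 or 3406, and the other named genes not without 3 or more of the animals, 3405 and 3406 among them.

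Over the mean of the regions the myelin list had a median log2 of -0.70 with 14 of 14 members below 0 (adjusted p = 3.07e-23, and 0.263 with an estimated correlation), and the cholesterol synthesis list -0.26 (2.13e-06, and adjusted p = 0.550 with an estimated correlation). Neuron and synapse genes (-0.11, adjusted p = 0.000271), heat shock genes (-0.16, 0.000745), interneuron genes (-0.05, 0.0359), glucocorticoid-responsive genes (-0.21, 0.0359), oxidative phosphorylation genes (-0.04, 0.0416) and vascular endothelium genes (-0.15, 0.0443) were also lower. Microglia genes (0.15, 0.00251) and reactive gliosis genes (0.18, 0.0135) were higher. None of these 10 lists passed with an estimated correlation, where adjusted p ran from 0.263 to 0.642.

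Without 1 animal, adjusted p reached 0.116 for microglia (3403), 0.206 for reactive gliosis (3389 or 3405), 0.206 for interneuron genes (3389, 3403, 3405 or 3396) and 0.505 for glucocorticoid-responsive genes (3363, 3403 or 3396). It reached 0.190 for oxidative phosphorylation (3363, 3389, 3405 or 3396) and 0.149 for vascular endothelium (any but 3405). Medians moved to 0.09 for microglia without 3403, -0.03 for oxidative phosphorylation and -0.09 for heat shock without 3363, -0.13 for glucocorticoid-responsive genes without 3403 or 3396, and -0.10 and -0.17 for interneuron genes without 3363 and 3406. After quantile normalization it was 0.607 for oxidative phosphorylation, 0.0814 for glucocorticoid-responsive and 0.0999 for interneuron genes, and after median scaling 0.0672 for vascular endothelium.

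GABA genes themselves did not pass as lists. The GABA synthesis, transport and breakdown list had medians of -0.07, -0.13 and 0.03 in hippocampus, cerebellum and cortex (adjusted p = 0.469, 0.872 and 0.987), and all of its 7 measured members did not pass in any region, among them Gad1, which makes GABA, at 0.16 ± 0.10 in cortex. The GABA vesicle transporter gene Slc32a1 had -0.30 ± 0.20 in hippocampus and -0.39 ± 0.20 in cortex. GABA receptor subunits had medians of -0.07, 0.01 and 0.05 in the same order (adjusted p = 0.715, 0.747 and 0.866). Glutamate receptor, transport and metabolism genes had medians of -0.17, -0.01 and -0.000561 (0.106, 0.747 and 0.822), and glutathione and oxidative stress defence genes 0.06, 0.06 and 0.01 (0.715, 0.747 and 0.532). Hmox1, haem oxygenase, stood at 0.61 ± 0.16 in hippocampus and 0.60 ± 0.16 in cortex and passed over the list alone in both, but not over all probe sets (adjusted p = 0.196 and 0.156).

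The unfolded protein and amino acid stress list did not pass, with medians of -0.04, 0.09 and -0.03 in hippocampus, cerebellum and cortex (camera adjusted p = 0.715, 0.747 and 0.810). In hippocampus its mean, 0.05, had the opposite sign, and Atf3 (0.72 ± 0.19) and Ddit3 (0.82 ± 0.23), transcription factors induced by stress, rose when adjusted over the list alone. Other lists that did not pass over the mean of the regions were thalamus and hypothalamus (median 0.12, adjusted p = 0.219), choroid plexus (0.30, 0.219), cell proliferation (0.14, 0.226) and pericyte, smooth muscle and meninges (-0.10, 0.473). Immature neuron (-0.06, 0.0836), hippocampus (0.03, 0.883), cerebellum (0.03, 0.692) and cortex markers (0.13, 0.983) did not pass either. Astrocyte genes (0.02, 0.602), activity-regulated genes (0.01, 0.642) and oligodendrocyte precursor genes (0.02, 0.748) had medians above 0 and means of -0.03, -0.01 and -0.08, and their tests pointed down. Of the astrocyte genes, Aldoc (-0.24 ± 0.06) and S100b (-0.40 ± 0.12) fell when adjusted over the list alone. GABA receptor subunits had a median of -0.07 and a mean of 0.05 in hippocampus, where Gabra6 (0.89 ± 0.27) rose when adjusted over the list alone. That Gabra6 probe set read only 14.7 ± 3.87 in WT hippocampus, near the floor of 9.46. The mean of the other Gabra6 probe set there, 3.05, lay under the floor. Striatum and red blood cell lists, each with 4 measured members, were not tested (medians -0.09 and -0.21), and included Tac1 (-0.69 ± 0.18) and the erythrocyte anion exchanger gene Slc4a1 (-0.59 ± 0.24).

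Neighbours of Aldh5a1 on chromosome 13 were compared with the rest because a targeted allele can carry linked DNA of the strain it was made in. Of the 79 probe sets whose genes lie within 20 Mb, 0 passed by limma in hippocampus, cerebellum, cortex or the mean of the regions, against 10, 3, 20 and 14 of 7467 outside (Fisher's exact test, two-sided, p = 1 in each). So few probe sets passed that 0 of 79 was likely in any case, and these counts cannot decide about linked DNA. An unadjusted p under 0.05 was found for 6, 7, 6 and 6 of the 79, or 7.59%, 8.86%, 7.59% and 7.59%, and for 8.46%, 12.2%, 10.2% and 10.1% outside. Of the 20 within 5 Mb, 0 passed in any of them, and an unadjusted p under 0.05 was found for 1, 4, 1 and 3, against 8.46%, 12.1%, 10.2% and 10.1% outside, so the share inside was higher in cerebellum and in the mean (Fisher p = 1, 0.294, 0.715 and 0.447). Idi1, Acot13, Jarid2, Psmg4, Nrsn1 and Sox4 were lowest by p in the mean of the regions, with log2 differences of -0.59, 0.26, 0.31, 0.31, -0.21 and 0.21 and adjusted p from 0.319 to 0.440. Without WT animal 3405, 1 neighbour passed.

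The genotype difference itself differed between regions for 4 probe sets, tested as an interaction. Mal had log2 differences of -1.39 in hippocampus and -1.73 in cortex but -0.02 in cerebellum, and Mobp -1.05, -1.40 and 0.11 in the same order. Lst1 went the other way, with 0.28, 0.82 and -1.58. Septin4, on 1 of its probe sets, had -1.67 in hippocampus, 0.27 in cortex and 0.94 in cerebellum. Each had an adjusted p of 0.0287 by limma's moderated F test, and the count was 4 without the animal as a block too; 896 had an unadjusted p under 0.05.

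Next by p were another Mobp probe set and Nsf, a vesicle fusion ATPase (both adjusted p = 0.0909), then Cacna1g (0.183), and Nfix, Spin1 and Gfap (each 0.192), none of which passed. Gfap stood at 0.99 ± 0.29 in hippocampus, 0.68 ± 0.29 in cortex and -0.33 ± 0.29 in cerebellum. The count of 4 was 0 without animal 3363, 3389, 3403 or 3406, and 0 when the spread was not modelled on intensity. Among the lists, myelin differed between cerebellum and hippocampus by 0.45 (adjusted p = 5.15e-07, and 0.326 with an estimated correlation) and between cortex and cerebellum by -0.53 (4.27e-09, and adjusted p = 0.608 with an estimated correlation). Of 26 lists, 0 differed between cortex and hippocampus by camera, where the smallest unadjusted p was 0.0102 (heat shock).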

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

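The tests of explanations below were chosen after the result was seen, except the exchange of WT region names, which was set beforehand. The ATF4 targets were listed before their own values were seen, but to explain a rise of Atf5 and Nupr1 already seen.

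A difference between regions in the KO effect, tested as an interaction in limma, singled out Lst1, Mal, Mobp and Septin4, each with an adjusted p of 0.0287. Between cerebellum and hippocampus, camera found 7 lists whose KO effect differed, with 0 remaining at an estimated correlation, where adjusted p ran from 0.317 to 0.670. The median difference, cerebellum minus hippocampus on the log2 scale, was 0.29 for cholesterol synthesis, 1.93 for choroid plexus, -0.26 for microglia and 0.18 for mitochondrial oxidative phosphorylation. It was 0.45 for myelin and mature oligodendrocyte genes, -0.19 for neuron and synapse genes and -0.29 for reactive gliosis. Between cortex and cerebellum 4 lists differed and 0 at an estimated correlation (adjusted p 0.608 to 0.677). The median difference, cortex minus cerebellum, was -1.18 for choroid plexus, -0.15 for mitochondrial oxidative phosphorylation, -0.53 for myelin and mature oligodendrocyte genes and 0.21 for neuron and synapse genes.

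Myelin genes were lower as a list in KO hippocampus and cortex, with adjusted p = 0.0714 and 0.0446 with an estimated correlation, so that only the cortex call holds there. In cortex the Gapdh 3'/5' ratio also set the genotypes apart, at 0.804 ± 0.00773 in KO and 0.903 ± 0.0202 in WT, while in hippocampus it was 0.844 ± 0.0547 and 0.841 ± 0.0429. RNA integrity was not tested as an explanation of the cortex change and is not excluded. Array-wide scaling is argued against: of the list medians under quantile normalization and median scaling in both regions, the one nearest to 0 was -0.80. Less white matter or fewer oligodendrocytes in the KO samples stays open and cannot be told apart from lower expression per cell. The lineage factors Sox10 and Myrf had a mean log2 difference of -0.21 over both regions and lay 2.21 to 4.77 SE above the list median, but these 2 genes, of which Sox10 is also expressed in precursor cells, do not decide it. Dissection, which no label describes, was not tested.

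Atf5 and Nupr1 were higher in KO hippocampus, and Atf5 in KO cortex. Dim signals near the floor are argued against, since the highest adjusted p of these calls with no floor or with 16 added was 0.00381, and array-wide scaling likewise, with 0.00193 as the highest under both scalings. An amino acid stress response through ATF4 is a candidate explanation: of 36 other ATF4 targets listed, 26 were measured, with a median log2 difference of 0.17 in hippocampus (20 above 0, camera adjusted p = 0.00339 over 4 comparisons). With an estimated correlation that adjusted p was 0.119, and Slc38a2, a target, had -0.36. The list fixed beforehand that comes nearest, unfolded protein and amino acid stress, did not pass. Its medians were -0.04 in hippocampus and -0.03 in cortex (camera adjusted p = 0.715 and 0.810). That list mixes unfolded protein genes with amino acid stress genes, so it does not test an ATF4 response alone. The explanation therefore stays a hypothesis.

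In cerebellum, leaving out the array of WT 3405 raised the counts to 62 higher and 102 lower. Lower RNA integrity of the other WT arrays is argued against by a mean Gapdh 3'/5' ratio of 0.794, under the 0.816 ± 0.0224 of the other 4. Uneven choroid plexus is not decided by Ttr. WT 3396 read 1112, inside the KO range of 266 to 1237, but WT 3406 read 88.1 and WT 3405 read 27.0, below that range. KO tissue on the WT 3405 array is argued against by its Gsn signal of 781, above the highest KO signal of 657, and its Atf5 signal of 47.5, under the lowest KO signal of 67.3. Why the counts rise without the WT 3405 array stays open, and no biological explanation was tested.

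With 3 animals against 3 there are 10 splits, too few for a share under 0.05. In hippocampus 1 of 10 splits, the real one, gave as many calls, 10 against at most 0 in the others; in cortex it was 1, with 24 against 2. For the mean of the regions it was 1, with 15 against 0, for the interaction 1, with 4 against 0, and for the lists 1, with 28 against 24. The other splits gave from 5 to 24 list calls at the preset correlation. Many such calls can therefore arise from groupings that do not follow genotype. In cerebellum 2 splits gave 3 calls, the other setting 3363, 3405 and 3406 against the rest. For the WT regions, 1 of 36 exchanges of region names within animals, the real one, gave as many as 3299 probe sets. The highest other gave 1097. That share is under 0.05 but is the smallest that 36 exchanges can give, so it argues against chance without excluding it.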

How the results depend on the processing

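Only the omission of the cerebellum array of WT 3405 was chosen after seeing the data. Of 39 gene calls, 0 reversed in the 15 settings that give gene calls, of which the 60th percentile filter covers 34 and only the region's 6 arrays 28. In most of these settings no reversal was possible. The called genes had KO and WT values that did not overlap, so leaving out 1 animal could not change the sign. The filters, the intensity trend, the block and the region's own arrays leave the log2 difference unchanged. Of the 39, 39 passed after quantile normalization, 38 after median scaling, 17 with no filter, 22 with no intensity trend and 37 with the animal as a block. Without 1 animal 28 (3363), 20 (3389 or 3403), 12 (3405), 16 (3406) and 32 (3396) passed. On the region's 6 arrays 2 of 28 passed, Kcne1l in hippocampus and Scd1 in cortex. With no floor or with 16 added, each count stayed within 1.5 times its value, except the lists that passed in cerebellum, 3 in place of 5 in both. For the changes below the cause was not tested. Signal near the floor limits the dim probe sets.

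After quantile normalization, 10 probe sets were higher in cortex and 18 lists passed in place of 28. Median scaling gave 6 lower in cerebellum and 21 lower in the mean of the regions. No filter gave 5 higher in hippocampus, 2 in cerebellum and 12 in cortex, 3 lower in the mean and 2 in the interaction. The 60th percentile filter gave 2 higher and 7 lower in cerebellum, and 18 lists. No intensity trend gave 1 lower in cerebellum, 1 higher and 0 lower in the mean, and 0 in the interaction. With the animal as a replicate block, 10 were higher and 28 lower in the mean. Only the region's 6 arrays, fewer samples, gave 0 higher and 1 lower in hippocampus, 0 lower in cerebellum, and 1 higher and 2 lower in cortex. With an estimated correlation 1 list passed. Without the cerebellum array of WT 3405, 62 were higher and 102 lower in cerebellum. Tests of Aldh5a1 were not run in any setting, since no probe set was assigned to it.

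With each animal left out in turn, counts ranged from 2 to 7 higher and 1 to 18 lower in hippocampus, 0 to 54 and 0 to 67 in cerebellum, 2 to 8 and 4 to 27 in cortex, and 1 to 7 and 1 to 20 in the mean. They ranged from 0 to 6 in the interaction, 1596 to 2276 for the WT regions, 21 to 28 lists and 0 to 1 neighbours. Of genes that had not passed, 7 changed sign, none past the threshold (log2 ranges): Alas2 (-0.11 to 0.32) and Fezf2 (-0.000948 to 0.78) in cerebellum, Ttr (-1.29 to 0.0636), Nr4a2 (-0.11 to 0.29) and Gabrb1 (-0.10 to 0.00288) in cortex, and Igf2 (-0.87 to 0.0146) and Igfbp2 (-0.82 to 0.0608) in hippocampus.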

Other observations

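The tests of genes without the WT 3405 cerebellum array were chosen after the result was seen; the list of ATF4 targets was set before its values were seen.

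With the cerebellum array of WT 3405 left out, the 6 higher genes of lowest p in cerebellum by limma were Ddx6, Ago2, Xrn1, Synrg, Gpcpd1 and Ppargc1a, which no list fixed here groups. Ddx6, an RNA helicase of processing bodies, had a log2 difference of 2.46 ± 0.28 (adjusted p = 0.000358), against 1.81 with all arrays. Ago2, of the silencing complex, had 1.99 ± 0.22 (0.000358), with signals of 333 as the KO mean, 303 in WT 3405, 120 in WT 3406 and 58.1 in WT 3396. Xrn1, an exonuclease that degrades mRNA, had 2.17 ± 0.28 (0.0016). Ppargc1a, a coactivator of mitochondrial genes, had 2.21 ± 0.37, and Gpcpd1 2.37 ± 0.39 (both 0.00908), and Synrg had 1.30 ± 0.21 (0.00775). Klf13 had -0.98 ± 0.15 (0.00775), and Mknk2, a kinase that acts on translation initiation, -0.81 ± 0.13 (0.00908). WT 3405 lay at a median of 0.728 of the way from the other WT arrays to the KO mean over the genes called. These genes were called on KO against the other WT arrays, with WT 3405 left out because calls rose without it. Its position is therefore partly set by that choice and is not evidence that it resembles KO.

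Among the 26 measured ATF4 targets, 0 passed over all probe sets in limma. Adjusted over the list alone, Slc7a5, the light chain that pairs with Slc3a2 in amino acid transport, was higher in hippocampus (0.59 ± 0.15) and cortex (0.57 ± 0.15). Lars, a leucyl-tRNA synthetase, was higher in hippocampus (0.35 ± 0.10). Wars, another tRNA synthetase (0.66 ± 0.15), the arginine transporter gene Slc7a3 (0.92 ± 0.24) and Pck2 (0.58 ± 0.18) were higher in cortex. The list had a median of 0.14 in cerebellum, 0.09 in cortex and 0.14 over the mean of the regions (camera adjusted p = 0.0157, 0.0134 and 0.000652 over 4 comparisons, and adjusted p = 0.135, 0.135 and 0.119 with an estimated correlation).

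Xist, expressed from the inactive X chromosome, lay below the Y-linked Eif2s3y in all 3 regions of 2 animals, KO 3363 and WT 3405 (Xist 2.41 to 15.2, Eif2s3y 71.4 to 183), and above it in the other 4 (Xist 127 to 493, Eif2s3y 0.748 to 10.1). The labels give no sex, and each genotype held 1 animal of the first pattern.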
